A study of Mus musculus with 6 samples.

How the data were processed

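RNA was sequenced from sorted DN3 thymocytes in 6 libraries, 2 each from control, p45-deficient and Tcf1-deficient mice. Per the submitters' processing notes, the tools named are TopHat2 (version not given in the sources used here), featureCounts 1.5.0-p3 and DESeq2 3.4, and the genome build is mm9. The notes give neither the role nor the order of these tools. The deposited files hold whole-number read counts per gene symbol, not normalised, as the authors counted them, with 24015 symbols in each. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical gene copies, may not be separated. Counts are per gene and do not separate Tcf7 isoforms. The reference annotation at hand is for another build (GRCm38.p6), so no coordinates are printed. It was used only to find the chromosome of each gene and the neighbours of Tcf7, for which 12897 of the 12939 tested symbols had a match.

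Samples were grouped by the genotype in their labels. Library totals ran from 19640524 to 28107031 counts. The ribosomal RNA gene Rn45s took 0.482% and 1.24% of counts in control, 1.43% and 1.51% in p45-deficient and 2.52% and 1.22% in Tcf1-deficient replicates 1 and 2. Within each group the 2 libraries differed by more than counting noise alone, with a chi-square per degree of freedom of 38.7 in control, 9.79 in p45-deficient and 73.1 in Tcf1-deficient. Each library was used as its own replicate, although separate preparations of 1 sample could differ this way too. The SD of the log2 difference between the 2 libraries was 0.51, 0.49 and 0.787. In a principal component analysis the first component (51.5% of variance) set the p45-deficient libraries apart, and the second (24.7%) set Tcf1-deficient replicate 1 apart.

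Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, leaving 12939. Libraries were scaled with TMM, a model with 1 mean per group was fitted to all 6 libraries with robust quasi-likelihood dispersions, and each of the 3 comparisons was tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment within the comparison at 0.05. The model has 3 residual degrees of freedom, and the common biological coefficient of variation was 0.215. SEs of log2 fold changes were taken from the F statistic. CPM values use TMM-scaled library sizes. Means are given with the SD over the 2 libraries. With 2 libraries per group, an exact permutation test of one gene cannot go below p = 0.333, so no such test was used.

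The design, the rule for named genes and 23 gene lists with 522 symbols, of which 507 were in the files, were set before the data were examined. The lists cover T-lineage identity, HMG-box genes, Wnt and Notch targets, apoptosis, p53 targets, the cell cycle, early progenitors, other blood and thymic cell types, immediate-early genes, cytokine and chemokine receptors, interferon-stimulated genes, E proteins and sex-linked genes. Some genes stand in more than 1 list. Lists with at least 5 tested members (22 of 23) were tested with camera from limma 3.58.1, on log CPM with a prior count of 2 and a preset correlation of 0.01, and again with a correlation estimated per list. With an estimated correlation, camera also takes its degrees of freedom from the residuals of the model (3 here) rather than from the number of genes. A call lost in that form need not be due to correlation between genes alone. Per list, the members called over all genes and adjusted over the list alone were counted. Named genes are Tcf7, the 8 largest rises and 8 largest falls per comparison among called genes with at least 5 CPM in the higher group and libraries that do not overlap, up to 4 members of each list with the smallest p in the comparison, and 5 sex-linked genes. Values of a gene named in one comparison may be given in another. Cd4, Nnt, and the mature T cell and double-positive thymocyte genes of the closing section were chosen after their values had been seen or for a later test. Folds against a group with 0 counts were computed against a floor of 3 counts over the group.

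The test was run on simulated data drawn from the mean level of each gene over the 6 libraries, the fitted dispersions and the real library sizes, with 200 changed genes. The changed genes were picked only from those with a mean of at least 2 CPM. For p45-deficient against control the test recovered 7.46% of 1.5-fold, 43.3% of 2-fold and 92.4% of 4-fold changes. It made 17 false calls among 12939 genes, beside 5, 29 and 61 true calls at these folds. Values were 7.46%, 56.7% and 90.9% with 13 false calls for Tcf1-deficient against control, and 5.97%, 50.7% and 83.3% with 12 false calls for Tcf1-deficient against p45-deficient. In a further simulation with 1 list raised 1.5-fold, camera with the preset correlation called that list in each comparison. It also called 1 unshifted list in p45-deficient against control and 0 in the other comparisons. For the shared controls, 20 sets of unchanged groups were simulated. Alternatives were RLE, upper-quartile and library-total scaling, no filter, a CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, the replicate number as a block, only the 4 libraries compared, a 2-fold minimum, an adjusted p below 0.01, and each library left out in turn. Alternatives chosen after seeing the data were a term for the split on immediate-early genes, the removal of Rn45s, and the counts of list members called without single libraries. Simulated directions of change for genes called in p45-deficient cells, and the fold changes and SEs with the split term, were also added after the data were seen.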

Results

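Gene expression was measured by RNA sequencing in DN3 thymocytes of the mouse, the stage at which developing T cells, still without surface CD4 and CD8, rearrange the T cell receptor beta locus. The cells had been sorted for low CD44 and high CD25 after removal of other blood lineages. The 6 libraries fell into 3 groups of 2. Control libraries came from wild-type mice. p45-deficient libraries came from mice lacking the long isoforms of Tcf1, the HMG-box transcription factor encoded by Tcf7, while the short isoforms are left in place. Tcf1-deficient libraries came from mice in which Lck-Cre removes all Tcf1 proteins from T-lineage cells. The deposited files list read counts for 24015 gene symbols. Library totals were 19640524 and 25704385 counts in control, 28107031 and 21826476 in p45-deficient and 22878258 and 23820767 in Tcf1-deficient cells. A count of 3 in one library corresponded to between 0.107 and 0.153 CPM, the count of a gene relative to the size of its library, and 12939 genes carried enough counts to be tested. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Floors cover counting error only, and SDs and SEs cover the spread between these libraries.

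Tcf7 itself was read first as a check of the labels. It stood at 2088 and 1810 CPM in the control libraries, 2340 and 2414 CPM in the p45-deficient libraries and 979 and 976 CPM in the Tcf1-deficient libraries. In p45-deficient cells the level was close to control (log2 fold change 0.29, SE 0.11, adjusted p = 0.115 by edgeR's quasi-likelihood test), which the labels leave open, since counts per gene do not separate long from short isoforms. In Tcf1-deficient cells both libraries lay below both controls (log2 fold change −0.995, SE 0.11), but the adjusted p was 0.0762, the smallest value in that comparison, which other genes shared. The same test passed without Tcf1-deficient replicate 1 (adjusted p = 0.0404) and without Tcf1-deficient replicate 2 (adjusted p = 0.00359), and by DESeq2 (adjusted p = 4.61e-12) and with no filter (adjusted p = 0.00249). It did not pass in the other alternatives, up to an adjusted p of 1 without control replicate 1. Against p45-deficient cells the Tcf1-deficient level was lower, by edgeR's test, with a log2 fold change of −1.28 (SE 0.11, adjusted p = 0.0031). Counts over exons outside the deleted part are included, so the remaining reads do not measure remaining protein. All 6 libraries carried Y-linked transcripts, with 1462 to 2803 counts of Ddx3y, and 4 to 13 counts of Xist.

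**Figure D1:**
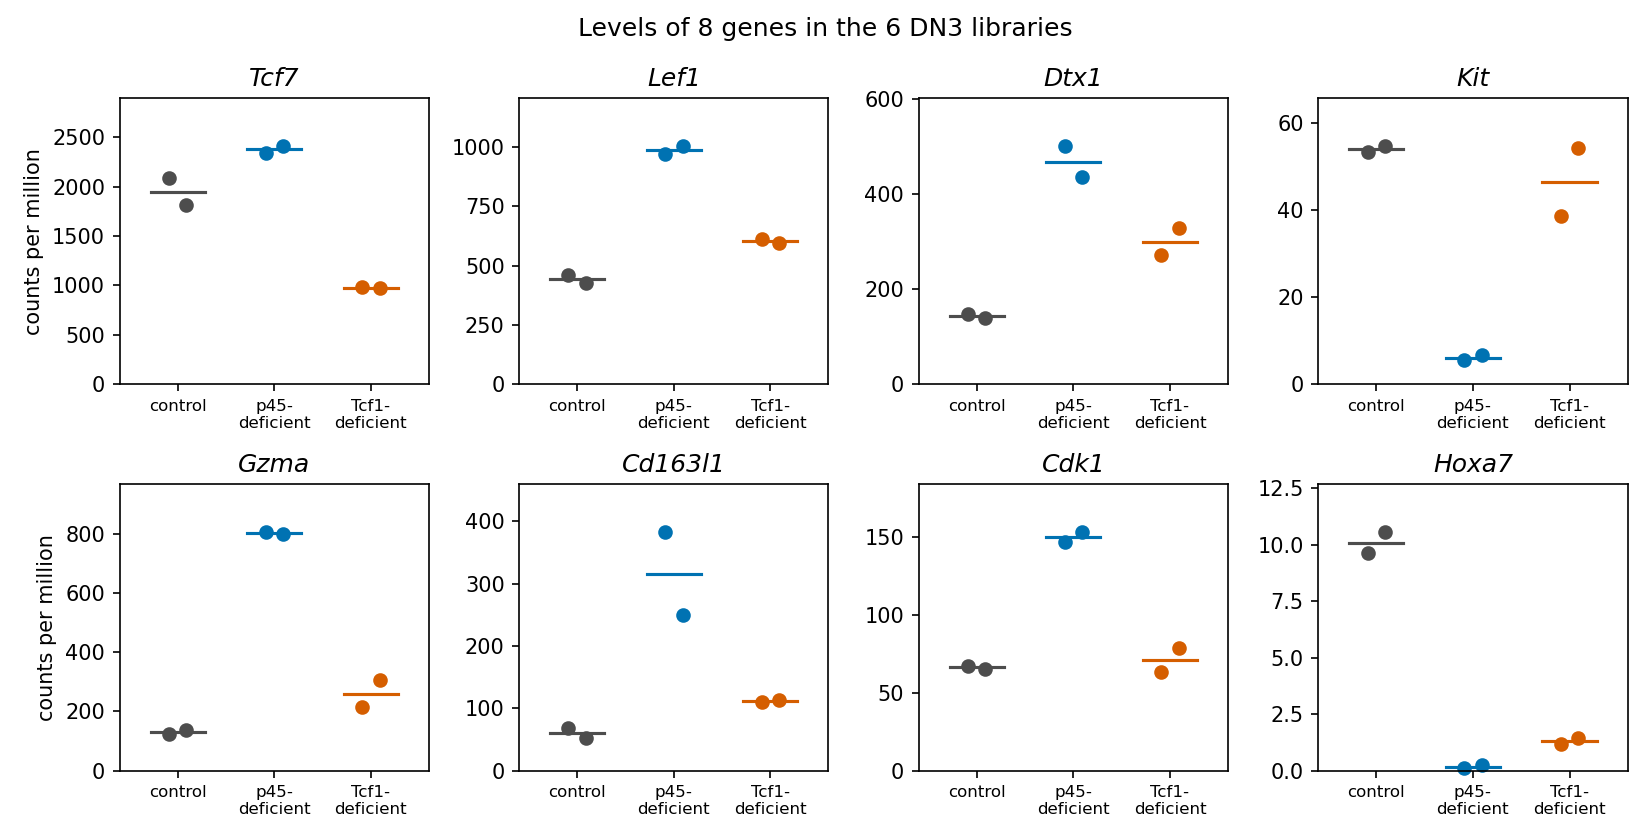
CPM (vertical axes, linear, from 0) of 8 genes in the control, p45-deficient and Tcf1-deficient groups, with 1 point per library and a line at the mean of the 2 libraries. Kit lay at 5.55 and 6.65 CPM in the p45-deficient libraries against 53.4 and 54.8 CPM in the controls, and Gzma at 807 and 799 CPM against 123 and 136 CPM.

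The comparison of p45-deficient with control cells asks what DN3 cells lose or gain without the long Tcf1 isoforms. Of the 45 measured cell-cycle genes, 29 rose and 1 fell. Of 23 regulators of the early progenitor stage, 9 fell, 1 rose and 13 were not called. Kit, the receptor for stem cell factor, went from 54.1 ± 0.984 CPM in control to 6.1 ± 0.781 CPM in p45-deficient cells (mean ± SD, n = 2 each). The cytotoxic granule protease gene Gzma went the other way, from 130 to 803 CPM, a 6.19-fold rise. Lef1, the closest relative of Tcf7, rose 2.22-fold (log2 fold change 1.15, SE 0.11). In all, edgeR's quasi-likelihood test called 2073 genes at an adjusted p below 0.05, 1096 of them higher and 977 lower, and 929 of these differed at least 2-fold, with 382 higher and 547 lower. The split between higher and lower moved with the scaling: library totals alone gave 721 higher and 1281 lower, and upper-quartile scaling 820 and 1175. Between these scalings the median log2 fold change of all genes moved by over 0.1, from 0.0462 with TMM to −0.0599 with library totals, so a change of about that size in a single gene has no firm direction.

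Among the cell-cycle genes, Cenpa, which encodes the centromeric histone, rose 2.42-fold. The mitotic kinase gene Cdk1 rose 2.26-fold, from 67.4 and 65.4 CPM to 147 and 154 CPM. Hmmr rose 2.18-fold, and Top2a, a topoisomerase gene of dividing cells, 1.97-fold. The list's median log2 fold change was 0.793, and 37 members were higher and 1 lower when adjusted over the list alone. The camera test against all other genes, with a preset correlation between genes, gave an adjusted p of 3.78e-11, which became an adjusted p of 0.906 with an estimated correlation. The count of members called higher was 4, 3, 2 and 6 without control replicates 1 and 2 and p45-deficient replicates 1 and 2, and 36 and 38 without Tcf1-deficient replicates 1 and 2. The list itself stayed called by camera in each of these omissions, with an adjusted p of at most 5.19e-08. The list medians per library were −0.212 and −0.36 in control and 0.491 and 0.55 in p45-deficient cells, on a log2 scale relative to the mean of the 6 libraries.

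The early progenitor list holds regulators that T cell precursors switch off as they commit. Its median log2 fold change was −1.665, the same with members that had 0 counts in a group set at their bound. Besides Kit, the homeobox gene Hoxa7 fell from 9.62 and 10.6 CPM to 0.110 and 0.239 CPM. Bcl11a, a zinc-finger regulator of progenitor and B cell programmes, fell from 20.3 and 16.0 CPM to 0.441 and 0 CPM. Cebpb, a myeloid C/EBP factor gene, fell 8.65-fold, from 13.5 and 31.2 CPM in the controls to 1.91 and 3.30 CPM. In this list, adjusted over the list alone, 2 members were higher and 13 lower. The camera adjusted p was 3.88e-05, and the adjusted p was 0.728 with an estimated correlation. That correlation was 0.0395 here, against 0.57 for cell-cycle genes, and this form of the test also rests on the 3 residual degrees of freedom. The loss of the call therefore cannot be laid to correlation between genes alone. Members called lower over all genes numbered 3 to 5 without a control or p45-deficient library and 12 and 11 without Tcf1-deficient replicates 1 and 2. Dendritic cell and antigen-presentation genes lay lower as a list (median −1.383, camera adjusted p = 0.00118, adjusted p = 0.906 with an estimated correlation). Of its 18 members 2 were called, both lower, with the same count adjusted over the list alone, and none was called without any one of the control or p45-deficient libraries, while 9 and 7 were lower without Tcf1-deficient replicates 1 and 2. Control replicate 1 stood above control replicate 2 on this list (library medians 0.868 and 0.271) and on the B cell list (0.451 and 0.042). One of the 2 called, H2-DMb1, a chain of the peptide-loading molecule of MHC class II, stood at only 4.06 and 3.93 CPM in control and fell by a log2 fold change of 1.59 (SE 0.39).

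Among HMG-box genes, 1 of 10 rose and 2 fell. Lef1 was the one that rose, from 460 and 428 CPM to 969 and 1006 CPM. Sox12 fell 16.3-fold and Tcf7l2, another TCF family member, 3.21-fold. Sox12 kept its call in each of the 6 fits with a single library left out, but Tcf7l2 in only 2. The counts were 2 higher and 2 lower when adjusted over the list alone. Among Wnt pathway targets, 1 of 13 rose, again Lef1, and 1 fell, Zcchc12 (2.48-fold), as when adjusted over the list alone. Zcchc12 kept its call in 2 of the 6 fits with a single library left out, and Lef1 in all 6. Notch pathway targets moved both ways, with 5 of 17 higher and 3 lower. Dtx1, a Notch-induced ubiquitin ligase gene, rose 3.27-fold, Heyl rose 3.98-fold and Uaca 2.24-fold, while Dtx3 fell 2.66-fold. The Notch counts were 6 higher and 6 lower when adjusted over the list alone, and over all genes 2 to 4 higher and 1 to 3 lower without a control or p45-deficient library. Of the T-lineage identity and pre-TCR genes, 1 of 38 passed: the costimulatory receptor gene Cd27, higher by 1.53-fold and not called when adjusted over the list alone. This count hung on single libraries, with 10 higher and 7 lower without Tcf1-deficient replicate 1, 11 and 6 without Tcf1-deficient replicate 2, 1 lower without control replicate 2 and none without the other 3. Fyn (log2 fold change 1.07, SE 0.31, adjusted p = 0.0619) and Dntt (−0.53, SE 0.18, adjusted p = 0.0794) did not pass edgeR's test.

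Of 23 pro-apoptotic genes 4 rose and 3 fell. The BH3-only gene Bid rose (2.13-fold), as did the initiator caspase gene Casp8 (1.91-fold), whereas the BH3-only genes Bmf and Bbc3 fell 1.91-fold and 2.29-fold. Of 14 anti-apoptotic genes, 1 rose and 2 fell. Birc5, also a mitotic gene, rose 2.37-fold, and Bcl2l2 and Bag3 fell 2.02-fold and 3.47-fold. Of 23 p53 targets, Ptp4a3 rose (1.55-fold) and Bbc3 fell, and no others were called. Adjusted over the list alone, the counts were 5 higher and 3 lower for pro-apoptotic genes, 1 higher and 2 lower for anti-apoptotic genes and 0 for p53 targets. Most of these calls were lost without a single control or p45-deficient library: 1 or 2 pro-apoptotic genes were then higher and 0 or 1 lower, 1 anti-apoptotic gene was higher and 0 or 1 lower, and no p53 target was called. Without Tcf1-deficient replicates 1 and 2, in turn, 2 p53 targets were higher and 5 and 3 lower, 5 and 6 pro-apoptotic genes were higher and 3 lower, and 1 and 2 anti-apoptotic genes were higher and 2 lower. With the term for the immediate-early split given later, 1 pro-apoptotic and 1 anti-apoptotic gene were higher and none lower. None of these 3 lists passed camera, with adjusted p of 0.532 (pro-apoptotic), 0.895 (anti-apoptotic) and 0.943 (p53).

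Calls in the lists of other lymphocyte types and of receptors can be set against 2073 of 12939 over all genes. Of the lists counted here, only gamma-delta genes had a larger share of members called. Gzma was the 1 natural killer and innate lymphoid gene of 25 that rose. Of 14 gamma-delta T cell genes 3 rose and 1 fell. Cd163l1, a scavenger receptor gene known from gamma-delta T cells, rose 5.21-fold, Etv5 3.26-fold and the Src-family kinase gene Blk 2.26-fold, while 5830411N06Rik, a relative of Cd163l1, fell 2.31-fold. Among cytokine receptor and STAT genes, 2 of 33 rose and 2 fell. The receptor gene Il9r rose 4.31-fold and Socs2, a feedback inhibitor of cytokine signalling, 5.99-fold. Il10ra fell 2.43-fold and Stat5a 1.46-fold. The integrin gene Itgae rose 3.89-fold and Itga4 fell 1.65-fold, each the only member of the 24 chemokine receptor and adhesion genes called in its direction. Csf2ra, a subunit of the GM-CSF receptor, fell 3.38-fold and was the 1 of 16 myeloid genes called. Of interferon-stimulated genes 1 of 27 rose, Ifit2, by 2.35-fold. In the remaining lists the called members were 1 higher and 1 lower of 29 beta-selected genes, 1 higher and 1 lower of 14 B cell genes, 1 higher of 14 thymic stromal genes, 1 higher of 7 erythroid genes, none of 6 E protein and Id genes and none of 4 sex-linked genes. Single libraries moved these counts: without a control or p45-deficient library, gamma-delta genes had 1 to 3 higher and 0 to 2 lower, cytokine receptor genes 1 or 2 higher and 0 to 4 lower, chemokine receptor genes 0 or 1 in each direction, natural killer genes 1 or 2 higher, myeloid genes 1 or 2 lower, beta-selected genes none higher and 0 to 4 lower, B cell genes 0 or 1 in each direction, and interferon-stimulated, stromal and erythroid genes none. Without a Tcf1-deficient library they were larger, with 5 gamma-delta, 6 interferon-stimulated and 4 or 5 cytokine receptor genes higher and 8 or 7 cytokine receptor genes lower. Adjusted over the list alone, the counts were 4 higher and 1 lower for gamma-delta genes, 2 and 2 for cytokine receptor genes, 1 and 0 for natural killer, chemokine receptor, beta-selected, stromal and erythroid genes each, 0 and 1 for myeloid genes, 1 and 3 for B cell genes, 0 and 2 for E protein genes and 0 for interferon-stimulated genes. None of these lists was called by camera. The cytokine and myeloid lists had medians of 0.026 and 0.257 and means of 0.07 and 0.035, while camera's sign was negative. The p53 and anti-apoptotic lists had medians of 0.022 and 0.001 and means of −0.091 and −0.216.

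Several of the genes with the largest changes lay outside these lists. Adam19, a metalloprotease gene, went from 3.58 and 2.21 CPM to 406 and 382 CPM. Dsp, which encodes the junction protein desmoplakin, went from 0.774 and 0.305 CPM to 68.0 and 92.3 CPM, and Pdlim4 from 0.725 and 0.191 CPM to 86.8 and 84.4 CPM. In the other direction Arhgap32 went from 35.5 and 30 CPM to 0.257 and 0.335 CPM. Afap1l1 had 478 counts over the control libraries and 0 over the p45-deficient libraries, which makes it at least 175-fold lower against a floor of 3 counts over the group.

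Immediate-early and heat-shock genes, which respond to handling of cells as well as to signals, also lay lower in p45-deficient cells as a list (median −0.981, camera adjusted p = 0.0224, adjusted p = 0.981 with an estimated correlation). Of 25 members 2 were called over all genes, Jun (17.3-fold lower) and Jund (3.46-fold lower), and none over the list alone. The controls themselves stood apart on this list, with library medians of −0.777 and 0.67, against −0.835 and −1.023 in p45-deficient cells. The list was no longer called without control replicate 2 (adjusted p = 0.28), p45-deficient replicate 2 (0.088), Tcf1-deficient replicate 1 (0.0925) or Tcf1-deficient replicate 2 (0.0588), nor with library totals (0.0605) or a term for this split (0.3). Its members called lower numbered 15 and 6 without control replicates 1 and 2, 0 without either p45-deficient library and 1 without either Tcf1-deficient library. With that term, added after the data were seen, 467 genes were called, 435 of them among the 2073. The term is set by the 2 controls alone, so it compares p45-deficient cells with control replicate 1 and is no check apart from leaving out control replicate 2. The 2073 genes all kept their sign, and their median absolute log2 fold change was 0.911 before and 0.933 with the term. The median SE went from 0.17 to 0.208 and the residual degrees of freedom from 3 to 2. Kit stayed called (log2 fold change −3.13, SE 0.25, adjusted p = 0.0188 by edgeR). The list counts became 3 higher and none lower for cell-cycle genes, 4 lower for early progenitor genes, 6 lower for immediate-early genes and 0 for dendritic cell genes. Cell-cycle (adjusted p = 1.09e-07), early progenitor (9.68e-05) and dendritic cell genes (0.00131) stayed called by camera with the preset correlation, where the main fit gave an adjusted p of 0.906, 0.728 and 0.906 with an estimated correlation. Calls numbered 450 without control replicate 1, 535 without control replicate 2, 258 without p45-deficient replicate 1, 387 without p45-deficient replicate 2, 3857 without Tcf1-deficient replicate 1 and 3923 without Tcf1-deficient replicate 2. Of the 45 genes named here with a call, 15 kept it without each of the 6 libraries, namely Lef1, Sox12, Dtx1, Dtx3, Uaca, Birc5, Cenpa, Cdk1, Kit, Hoxa7, Gzma, Cd163l1, Csf2ra, Dsp and Arhgap32.

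**Figure D2:**
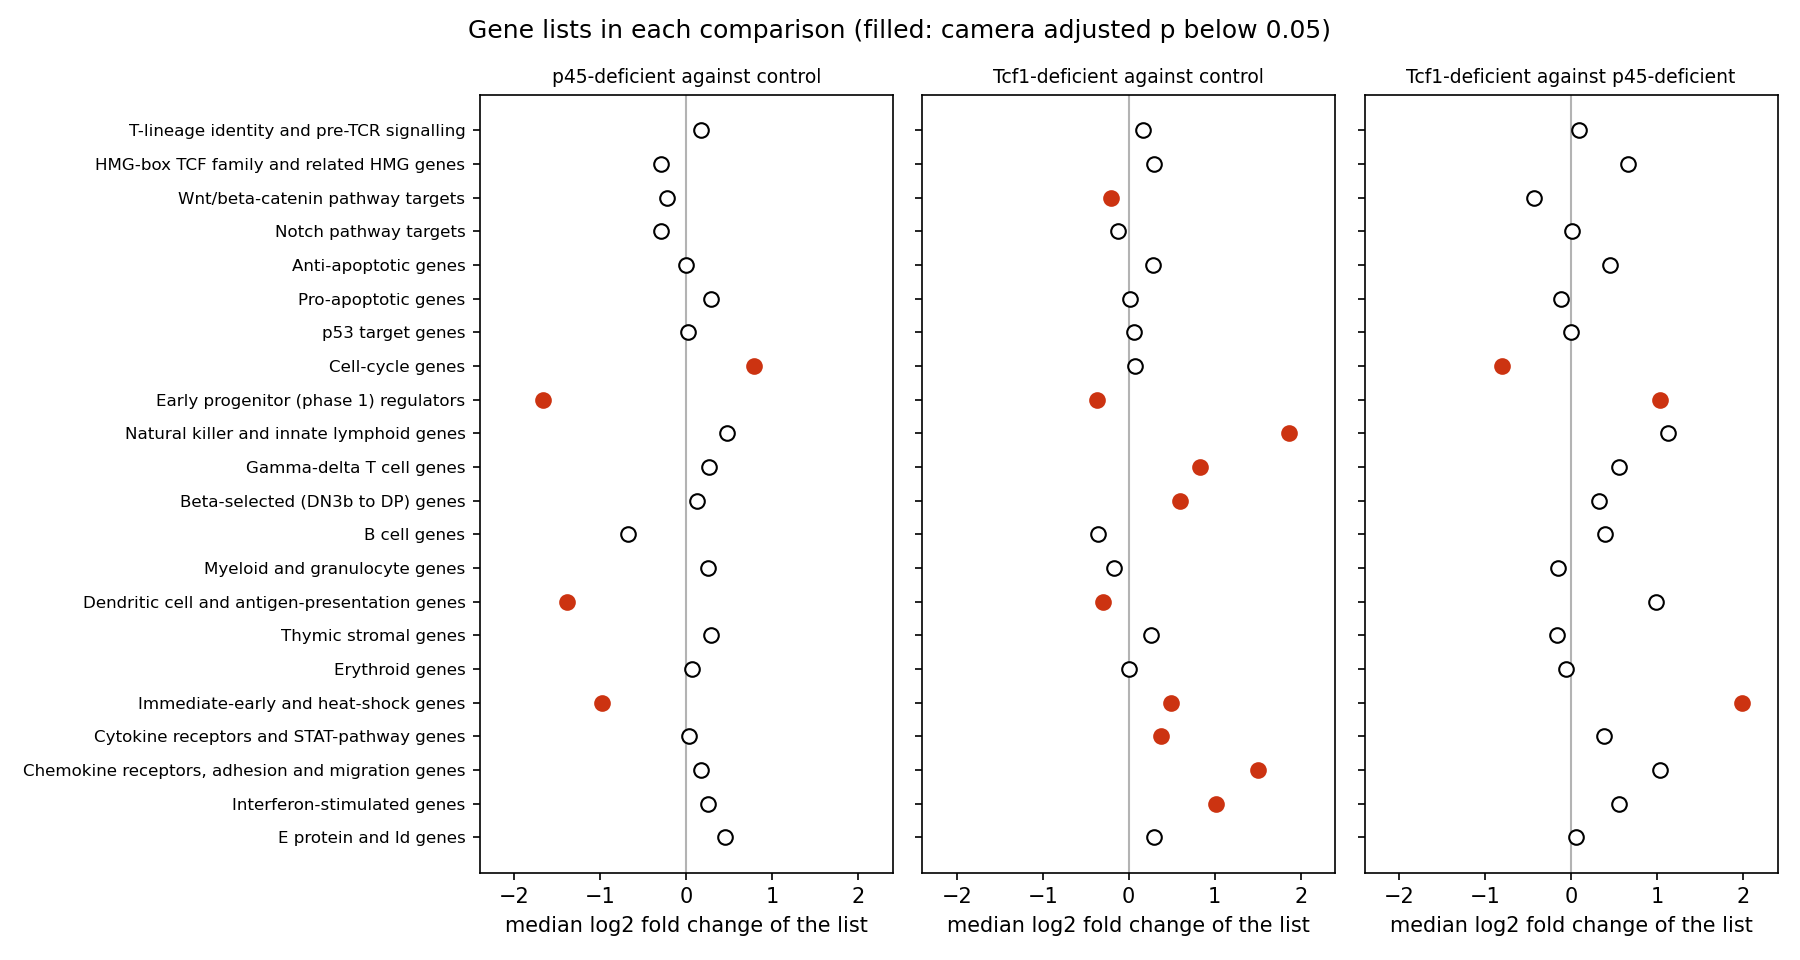
Median log2 fold change (horizontal axis) of the tested members of 22 gene lists in each of the 3 comparisons, with filled points for lists at a camera adjusted p below 0.05 under the preset correlation. Cell-cycle genes lay at 0.793 in p45-deficient against control and at −0.801 in Tcf1-deficient against p45-deficient cells; no list was called with an estimated correlation.

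The comparison of Tcf1-deficient with control cells asks what differs at the same stage in cells labelled as lacking all Tcf1. How complete the loss was in these cells was not measured. No single gene passed edgeR's test, limma-voom also called 0 and DESeq2 called 145 (79 higher and 66 lower). By edgeR 1024 of the 12939 genes had an unadjusted p below 0.05, where a share of 0.05 is expected with no change. The genes with the smallest p among those in the lists included Dtx1, at 271 and 328 CPM against 147 and 140 CPM in control (log2 fold change 1.06, SE 0.14, adjusted p = 0.111 by edgeR), and Hoxa7, at 1.19 and 1.46 CPM against 9.62 and 10.6 CPM (−2.93, SE 0.39, adjusted p = 0.111). Gzma stood at 215 and 306 CPM, a log2 fold change of 1.01 (SE 0.17). Etv5 had a log2 fold change of 1.48 (SE 0.30), Sox13, an HMG-box gene of gamma-delta T cells, 0.60 (SE 0.13), Lef1 0.44 (SE 0.11), Trib2 1.15 (SE 0.27) and Bmf −0.84 (SE 0.17). Kit lay at 38.6 and 54.4 CPM, near control, with a log2 fold change of −0.22 (SE 0.19). In simulated data with this design and 12939 genes, the test recovered 56.7% of 2-fold and 90.9% of 4-fold changes. The changed genes all had a mean of at least 2 CPM, so recovery below that level was not measured. The simulation gave all groups the same spread, whereas the Tcf1-deficient libraries differed more than the controls (SD of the log2 difference 0.787 against 0.51). In the data neither Hoxa7 nor the homeobox gene En2, with 1256 counts against 0 in control, was called. The simulated recovery may therefore overstate the recovery in the data.

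As lists, 7 lay higher in Tcf1-deficient cells and 3 lower by camera with the preset correlation, with 0 members called over all genes in each, and the adjusted p was 0.588 for all 10 with an estimated correlation. The higher lists were natural killer and innate lymphoid genes (median log2 fold change 1.861, adjusted p = 2.45e-08), interferon-stimulated genes (1.017, 1.58e-06), gamma-delta T cell genes (0.834, 2.17e-05), chemokine receptor and adhesion genes (1.508, 0.000559), immediate-early genes (0.494, 0.00154), cytokine receptor and STAT genes (0.381, 0.0127) and beta-selected genes (0.601, 0.04). The lists lower by camera were dendritic cell and antigen-presentation genes (−0.301, 0.00279), Wnt targets (−0.201, 0.0127) and early progenitor regulators (−0.373, 0.0252). The early progenitor median was unchanged with members at 0 set at their bound. Tcf7, the deleted gene, is itself 1 of the 13 tested Wnt members, and the list was not tested without it. Adjusted over the list alone, 5 of 14 gamma-delta T cell genes were higher, as were 1 of 25 natural killer genes and 1 of 24 chemokine receptor and adhesion genes, and 3 of 23 early progenitor genes were lower. For HMG-box genes those counts were 4 higher and 2 lower of 10, for Notch targets 2 higher of 17 and for Wnt and pro-apoptotic genes 1 in each direction. Cell-cycle genes had a median of 0.073, and 33 of 45 members were above 0 without a call. T-lineage, HMG-box, Notch, apoptosis, p53, B cell, myeloid, stromal, erythroid and E protein lists were not called by camera. The Notch list had a median of −0.122 and a mean of 0.129.

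Of the 7 higher lists, all but the immediate-early list had a library median above 0 in Tcf1-deficient replicate 1 and below 0 in replicate 2. Replicate 1 had a list median of 1.872 for natural killer genes, 1.426 for chemokine receptor and adhesion genes, 1.191 for interferon-stimulated genes and 0.682 for beta-selected genes, and replicate 2 had −0.173, −0.289, −0.37 and −0.032. Replicate 1 also held 372 CPM of Cd4 against 46.1 to 86.5 CPM in the other 5 libraries. In the gamma-delta list, Maf stood at 51.2 and 20 CPM against 6.91 and 5.46 CPM in control, and Cd163l1 at 110 and 114 CPM against 68.4 and 53 CPM. Nkg7, a granule protein gene, had 65.3 and 54.8 CPM against 24.0 and 38.5 CPM. The interferon-stimulated gene Usp18 had 33.9 and 14.8 CPM against 5.95 and 8.97 CPM, and the chemokine receptor gene Cxcr6 22.2 and 2.87 CPM against 2.03 and 2.48 CPM. The integrin gene Itgae had 62.0 and 35.7 CPM against 13.5 CPM in both controls. The immediate-early list stood high in both (1.175 and 0.813). The camera calls that follow use the preset correlation, and no list was called in the main fit with an estimated correlation. Without replicate 1, natural killer genes (adjusted p = 0.000533), gamma-delta genes (adjusted p = 0.0119) and immediate-early genes (adjusted p = 0.0131) were still called by camera, and interferon-stimulated (0.579), chemokine receptor and adhesion (0.395), beta-selected (0.762), cytokine receptor (0.672, sign reversed) and early progenitor genes (0.289) were not. Without replicate 2, dendritic cell (0.923), Wnt (0.788) and immediate-early genes (0.175) were not. Among the immediate-early genes Egr1 had 147 and 184 CPM and Ier2 144 and 118 CPM, against 29.4 and 94.1 CPM and 37.1 and 93.4 CPM in the controls. Without control replicate 1 that list's sign reversed (adjusted p = 0.304), and chemokine receptor (0.134), cytokine receptor (0.459), beta-selected (0.471), Wnt (0.0547) and early progenitor genes (0.0506) were no longer called. That left 4 of the 10 lists called: natural killer, gamma-delta, dendritic cell and interferon-stimulated genes. Early progenitor genes also lost the call without control replicate 2 (adjusted p = 0.0699), with library totals (0.0669) and with the CPM filter (0.0862), Wnt targets with the CPM filter (0.132), and beta-selected genes without p45-deficient replicates 1 (0.0571) and 2 (0.0579) and with the replicate block (0.0672). With the term for the immediate-early split, chemokine receptor (0.102), cytokine receptor, beta-selected and immediate-early genes (0.424 each) were not called. Single genes called numbered 16 without Tcf1-deficient replicate 1 and 894 without Tcf1-deficient replicate 2, where the remaining library was assumed to vary like the other groups, and 33 with no filter on low counts.

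**Figure D3:**
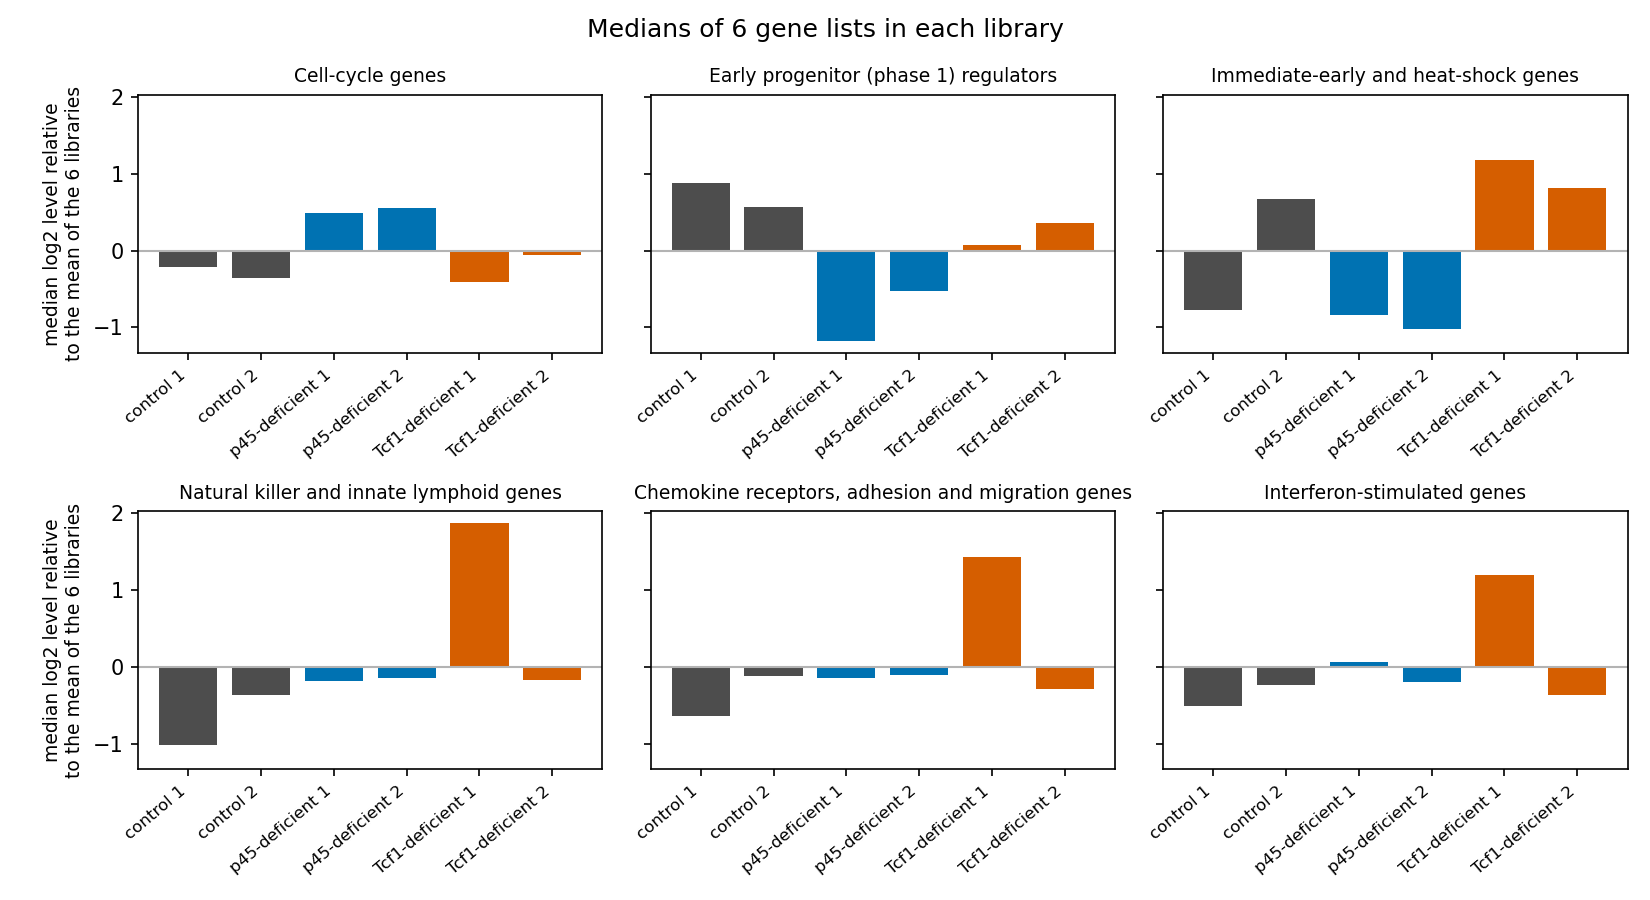
Median over list members of the log2 level relative to the mean of the 6 libraries (vertical axis), for 6 gene lists, with 1 bar per library. Natural killer, chemokine receptor and interferon-stimulated lists were highest in Tcf1-deficient replicate 1 (1.872, 1.426 and 1.191), and immediate-early genes were below 0 in control replicate 1 and both p45-deficient libraries and above 0 in the other 3.

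The direct comparison of Tcf1-deficient with p45-deficient cells tests whether the 2 mutant groups differ. It also tests the difference between the other comparisons, because the shared controls cancel. Of 45 cell-cycle genes 27 were lower in Tcf1-deficient cells and 1 was higher, and 26 of the 29 called higher in p45-deficient against control were among those lower here. Of 23 early progenitor genes 6 were called higher and 1 lower, and all 6 had been called lower in p45-deficient against control. Both comparisons rest on the same p45-deficient libraries with opposite sign. These overlaps therefore follow in part from the selection and are not independent support. Kit was 7.64-fold higher in Tcf1-deficient cells, with 46.5 ± 11.1 CPM against 6.1 ± 0.781 CPM (mean ± SD, n = 2 each), and Gzma was 3.08-fold lower. Rag1, of the recombinase, was 2.51-fold lower and Ptcra, the pre-TCR alpha chain, 2.22-fold lower, while 23 of the 38 T-lineage and pre-TCR genes were above 0 and that list was not called by camera (adjusted p = 0.994). edgeR's quasi-likelihood test called 1348 genes, 654 higher and 694 lower, and library totals alone gave 744 higher and 483 lower.

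Of the cell-cycle genes, Cdk1 was 2.12-fold lower, Hmmr 1.99-fold and Cenpa 1.79-fold. The single one higher was the D-type cyclin gene Ccnd2, at 529 and 469 CPM against 237 and 187 CPM. The list median was −0.801, the camera adjusted p was 1.37e-11 and the adjusted p was 0.905 with an estimated correlation. When adjusted over the list alone, 36 members were lower and 1 higher. Over all genes the count of members lower was 13 and 12 without control replicates 1 and 2, 0 without either p45-deficient library, 23 without Tcf1-deficient replicate 1 and 37 without replicate 2. Among early progenitor genes Nfe2 was 4.50-fold higher, Hoxa7 7.61-fold and Bcl11a 27.1-fold, with Bcl11a at 4.75 and 8.57 CPM against 0.441 and 0 CPM. That list's median was 1.028, the camera adjusted p was 0.00119 and the adjusted p was 0.905 with an estimated correlation. The list alone gave 8 higher and 1 lower, and over all genes 2 to 4 members were higher without a control or p45-deficient library. Of 38 T-lineage genes 3 were lower and none higher, the third being Thy1 (1.40-fold), and none of the 38 was called without any one of the control or p45-deficient libraries, while 2 were higher and 5 lower without Tcf1-deficient replicate 1 and 4 higher and 7 lower without replicate 2. Among 10 HMG-box genes Tcf7 and Lef1 (1.64-fold) were lower and Sox12 (5.69-fold) and Sox13 (1.71-fold) higher. Of 13 Wnt targets 2 were lower, the same Tcf7 and Lef1, and Zcchc12 was 2.57-fold higher. Of the 6 fits with a single library left out, Zcchc12 kept its call in 2, Lef1 in 4 and Tcf7 in 6. Counts adjusted over the list alone were 0 higher and 2 lower for T-lineage genes, 4 and 2 for HMG-box genes and 1 and 2 for Wnt targets.

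Notch targets again went both ways, with 3 of 17 higher and 5 lower. Dtx3 was 2.34-fold and the Notch effector gene Hes1 2.66-fold higher, while Uaca was 2.43-fold and Nrarp, a feedback inhibitor of Notch, 2.84-fold lower. Of 14 anti-apoptotic genes 1 was lower, Birc5 (1.95-fold), and of 23 pro-apoptotic genes 2 were lower, among them Bid (2.10-fold), with none higher in either list. The 2 gamma-delta scavenger receptor genes moved in opposite directions, 5830411N06Rik 3.23-fold higher and Cd163l1 2.82-fold lower. Of 25 natural killer genes 2 were higher, among them Nkg7 (2.56-fold), and Gzma was lower. Among 33 cytokine receptor and STAT genes, Il10ra (1.98-fold), Stat4 (1.83-fold) and Jak3 (2.09-fold) were higher and Il9r was 2.62-fold lower. Csf2ra was 2.71-fold, Cd96 1.78-fold and Itga4 1.72-fold higher. The remaining lists had called members as follows: 2 higher and 2 lower of 14 gamma-delta genes, 2 higher and 1 lower of 29 beta-selected genes, 1 higher and 1 lower of 16 myeloid genes, 1 higher of 23 p53 targets, 1 higher of 24 chemokine receptor and adhesion genes, 1 lower of 14 B cell, 18 dendritic cell, 14 stromal and 7 erythroid genes each, and none of the interferon-stimulated or E protein genes. Adjusted over the list alone, the counts were 4 higher and 5 lower for Notch targets, 0 and 4 for pro-apoptotic genes, 0 and 1 for anti-apoptotic genes, 2 and 1 for natural killer genes, 3 and 2 for gamma-delta genes, 4 and 1 for beta-selected genes, 8 and 2 for cytokine receptor genes, 1 and 1 for myeloid and stromal genes each, 0 and 1 for erythroid genes, and 0 for p53, chemokine receptor, B cell, dendritic cell, interferon-stimulated and E protein genes. Without a p45-deficient library at most 2 members of any of these lists were called in a direction, and without Tcf1-deficient replicate 2, 15 natural killer, 17 cytokine receptor, 14 chemokine receptor and 19 interferon-stimulated genes were higher. The lists of this paragraph were not called by camera. Median and mean differed in sign for T-lineage (0.086 and −0.012), p53 (−0.003 and 0.211), erythroid (−0.061 and 0.084) and E protein genes (0.061 and −0.004), and camera's sign was opposite to both for Notch and myeloid genes. Outside the lists, Arhgap32 was 35.3-fold and the metalloprotease-like gene Adam11 16.8-fold higher. The homeobox gene En2 had 1256 counts over the Tcf1-deficient libraries, at 17.9 and 35.3 CPM, and 0 over the other 4 libraries. The En2 count was at least 448-fold higher than in p45-deficient and at least 407-fold higher than in control cells, against a floor of 3 counts over the group. Engineered alleles can carry En2 sequence, and counts per gene do not show whether these reads come from the En2 locus.

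Immediate-early and heat-shock genes were also higher in Tcf1-deficient than in p45-deficient cells (median 1.991, camera adjusted p = 0.000103, adjusted p = 0.905 with an estimated correlation), with 4 of 25 members called higher over all genes and 14 higher and 1 lower when adjusted over the list alone. Over all genes 16 members were higher without either control library, 0 without either p45-deficient library, 1 without Tcf1-deficient replicate 1, 0 with the immediate-early split as a term, and 2 higher and 2 lower without Tcf1-deficient replicate 2. Jun was 23.6-fold, Jund 4.43-fold and Ier2 3.90-fold higher. The split on these genes puts both p45-deficient libraries on one side and both Tcf1-deficient libraries on the other, and a term for it left 0 genes called by edgeR, with 1630 at an unadjusted p below 0.05. The fold changes of the 1348 genes stayed about as large, with a median absolute log2 fold change of 0.997 before and 0.947 with the term and 1347 signs kept, and the calls ended as the median SE went from 0.18 to 0.31 and the residual degrees of freedom from 3 to 2. Kit had a log2 fold change of 2.93 (SE 0.21) before and 2.9 (SE 0.37, adjusted p = 0.195) with the term, and Tcf7 −1.28 (SE 0.11) and −1.08 (SE 0.18, adjusted p = 0.268). By camera with the preset correlation, cell-cycle (adjusted p = 2.27e-05) and early progenitor genes (0.00349) stayed called with the term and immediate-early genes did not (0.338), where the main fit gave an adjusted p of 0.905 for each with an estimated correlation. The replicate spread also weighed on this comparison, with 105 calls without p45-deficient replicate 1, 184 without p45-deficient replicate 2, 664 and 650 without control replicates 1 and 2, 3437 without Tcf1-deficient replicate 2 and 1365 without Tcf1-deficient replicate 1. DESeq2 called 2551 genes. Among the named genes, Tcf7, Kit, Gzma, 5830411N06Rik, Dtx3, Uaca, Arhgap32 and Adam11 kept their call without each of the 6 libraries. Nnt, chosen after its values were seen and given below, did so too.

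The fold changes of both mutants against control were then set side by side. Of the 1096 genes called higher in p45-deficient cells, 874 (79.7%) were also above 0 in Tcf1-deficient cells, and of the 977 called lower, 772 (79%) were below 0. Because both use the same controls, 10 simulations with unchanged Tcf1-deficient libraries, run after the result was seen, already gave 59.5% to 65.7% and 58.9% to 65.9% over the 2073 genes with the smallest p of each simulation. Over all genes 63.8% had the same sign, against 66.6% in simulations with both mutants unchanged. The genes called higher and lower had median log2 fold changes of 0.796 and −1.107 in p45-deficient and 0.16 and −0.223 in Tcf1-deficient cells, and 564 and 534 of them also differed between the mutants, with the Tcf1-deficient level nearer to control or beyond it. Adam19, for example, stood at 56.2 and 19.9 CPM in Tcf1-deficient cells, between the levels of the other groups. The test between the mutants uses the same p45-deficient libraries as the calls, so the 564 and 534 arise in part from that selection. Over all 12939 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.345. Simulated unchanged groups against the same controls gave a mean of 0.5 over 20 simulations. The covariance was 0.226 against a simulated 0.0868, a difference of 0.14. At an unadjusted p below 0.05 in both, 254 genes were higher in both mutants and 265 lower in both, where simulation gave 78 and 55.4 and independent lists would give 102 and 72.2, and 56 were opposite, where simulation gave 2.1 and independent lists 172. The 2 controls cannot be divided into 2 sets of 2, so part of the excess may come from the shared controls. All of these simulations drew genes independently of each other, so their values leave out variation shared between genes. Leaving out single libraries moved the correlation between 0.224 (without Tcf1-deficient replicate 1) and 0.493 (without control replicate 2).

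**Figure D4:**
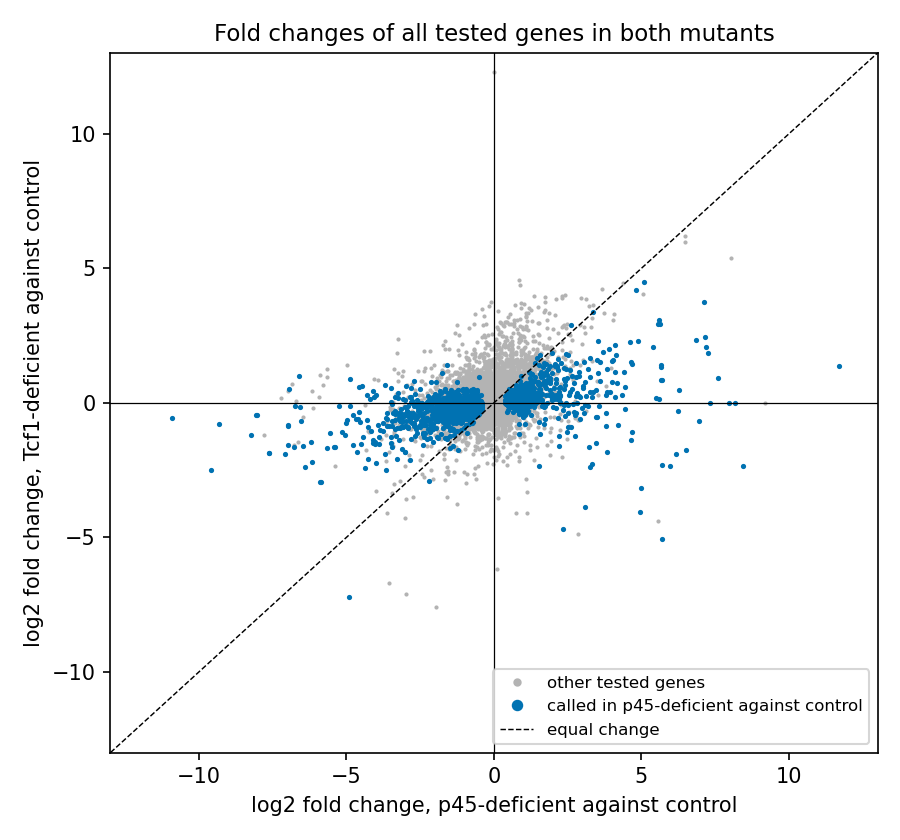
Log2 fold change of each tested gene in p45-deficient (horizontal axis) and Tcf1-deficient cells (vertical axis), both against the same controls, with the 2073 genes called in p45-deficient cells in blue and a dashed line at equal change. The called genes lie closer to the horizontal axis than to the line, with median log2 fold changes of 0.796 and −1.107 against 0.16 and −0.223.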

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

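The tests on the spread of Tcf1-deficient replicate 1, on the split of immediate-early genes and on a partial change were chosen only after the result was seen; the test on the chromosome of Tcf7 was written before. One result was picked out because the effects of both mutations, each against control, differed by a direct test. Between Tcf1-deficient and p45-deficient cells 1348 genes differed, while 2073 were called in p45-deficient against control and 0 in Tcf1-deficient against control by edgeR (145 by DESeq2).

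The pattern weighed is that more genes were called in p45-deficient than in Tcf1-deficient cells. Spread from Tcf1-deficient replicate 1 does not account for it alone: without that library 16 genes were called against control, and with 1 library of each mutant and both controls, where the spread comes from the controls alone and is the same for both mutants, the p45-deficient count was between 1676 and 2022, against 35 and 38 for Tcf1-deficient replicate 2 and 757 and 891 for replicate 1. Variants carried along with the p45 allele that change genes on their own chromosome could account only for calls that lie there. These were 184 of the 2070 calls with a known chromosome, which argues against them as the main source. Of the calls, 8.89% lay on the chromosome of Tcf7, which holds 8.37% of tested genes. The prediction written beforehand asked for most calls to lie there. So small a share of genes could hardly meet it, so its failure adds little. Of 59 tested neighbours 11 were called (18.6% against 16% elsewhere, Fisher's exact p = 0.593). These shares cannot test a carried variant that changes genes on other chromosomes, which stays open. The split on immediate-early genes is argued against as the whole source of the p45-deficient calls. With a term for it, edgeR still called 467 genes in p45-deficient cells, with 3448 at an unadjusted p below 0.05. In Tcf1-deficient cells against control it called 0, with 342 at an unadjusted p below 0.05, but 0 were called before the term too. The 342 are fewer than the share of 0.05 of 12939 tests expected with no change. The term is set by the 2 controls alone. It compares p45-deficient cells with control replicate 1 and Tcf1-deficient cells with control replicate 2. The 2073 genes all kept their sign, with a median absolute log2 fold change of 0.911 before and 0.933 with the term. A share of the difference from that split stays open, because calls also fell to 450 and 535 when single control libraries were left out, so the lower count with the term does not measure it. A partial version of the same change in Tcf1-deficient cells is a candidate explanation: over the 2073 called genes the slope of the Tcf1-deficient on the p45-deficient fold change, each against a different control library, was 0.16 and 0.19, where simulations with unchanged Tcf1-deficient libraries gave 0.0241 to 0.0588 over the 2073 genes with the smallest p of each. The simulations drew each gene independently, so variation shared between genes is left out and their range may be too narrow. The alleles also differ in when they act, p45 being absent in all cells and Lck-Cre acting within the T lineage, and this biological difference stays open as untested. How complete the deletion was in these DN3 cells was not measured, since the Tcf7 counts include exons outside the deleted part.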

How the results depend on the processing

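The term for the immediate-early split, the removal of Rn45s and the counts of list members without single libraries were chosen after seeing the data. Calls in p45-deficient against control (2073) ran from 1905 to 3069 under scaling, filter and tool changes, and were 3907 with only the 4 libraries compared, 929 at 2-fold, 462 at an adjusted p below 0.01, 467 with the split term and 258 to 3923 without single libraries. No called gene changed sign under any of these. In Tcf1-deficient against control (0 calls, 1024 at an unadjusted p below 0.05) there were 33 without the filter, 145 by DESeq2 and 0 to 894 without single libraries. In Tcf1-deficient against p45-deficient (1348) there were 2551 by DESeq2, 488 with only the 4 libraries, 673 at 2-fold, 169 at 0.01, 0 with the split term (1630 at an unadjusted p below 0.05, 1 called gene with its sign turned) and 105 to 3437 without single libraries. Fewer libraries leave fewer degrees of freedom, and the cause of the other moves was not tested. Lists called were 4, 10 and 3 in the 3 comparisons in the order above, 0 in each with an estimated correlation, and 3 to 5, 5 to 11 and 3 to 9 without single libraries. In Tcf1-deficient against control, immediate-early genes reversed without control replicate 1 (adjusted p = 0.304; 1.63e-16 without control replicate 2) and with the split term (0.424), cytokine receptor genes reversed without Tcf1-deficient replicate 1 (0.672; 3.62e-05 without replicate 2), and Kit turned to a log2 fold change of 0.01 without replicate 1 (−0.49 without replicate 2). Tcf7 against control (log2 fold change −1) passed without the filter, by DESeq2 and without either Tcf1-deficient library, each at −1 (range −1.1 to −0.89 over single libraries), and against p45-deficient cells it was −1.08 and no longer called with the split term. The correlation of both control comparisons (0.345) was 0.387 without the filter, 0.294 with the split term and 0.224 to 0.493 without single libraries. 

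Replicate numbers are shared between groups but do not pair the libraries: deviations of same-numbered libraries correlated at −0.0141, −0.0504 and −0.0286. With a replicate block, calls were 1613, 0 and 920 in the 3 comparisons (1554 and 886 shared with those above) and lists called 4, 9 and 5. Of 111 single gene results apart from Tcf7, 83 past the threshold, 162 gene and library combinations lost the call without a library and 23 gained one, against 108 and 26 under the other settings. Depth limits genes below about 0.15 CPM. In simulated data 1.5-fold changes were recovered at 7.46% or less, among changed genes with a mean of at least 2 CPM. The false share of calls there was above the 0.05 set by the threshold.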

Other observations

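Tests on genotype and handling were chosen only after the results were seen, as were the gene families, Nnt, the Cd8 genes and the single mature T cell genes named; the list of further mature T cell genes was written before its levels were read. Among 150 families of genes that share a symbol prefix, mitochondrial respiratory complex genes (Nduf) were higher in p45-deficient than in control cells, with 12 of 43 called higher and none lower (median log2 fold change 0.423, camera adjusted p = 5.24e-07, adjusted p = 0.733 with an estimated correlation). Mitochondrial ribosome genes (Mrpl) had 10 of 48 called higher (0.445, 7.92e-07), and centromere genes (Cenp) 13 of 19 (1.007, 1.33e-06), each with an adjusted p of 0.733 with an estimated correlation. In Tcf1-deficient against p45-deficient cells the same families were lower, with 11 Nduf, 9 Mrpl and 9 Cenp members called (camera adjusted p of 7.11e-08, 7.11e-08 and 1.22e-06, and an adjusted p of 0.709 for each with an estimated correlation). Both comparisons share the p45-deficient libraries, so this reversal is not independent of the rise. Nnt, a mitochondrial transhydrogenase gene that is known to differ between inbred strains, stood at 152 and 153 CPM in control, 159 and 156 CPM in p45-deficient and 64.5 and 72.2 CPM in Tcf1-deficient libraries (Tcf1-deficient against p45-deficient −1.21, SE 0.12, adjusted p = 0.00345 by edgeR; against control −1.16, adjusted p = 0.0762). 

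Tcf1-deficient replicate 1 carried genes of mature T cells. A list of 28 further such genes had a median log2 ratio of 2.1 over the other 5 libraries, 27 were higher and 24 were highest of the 6, where the median of all genes was 0. Lgals1 was lower (−0.3). Foxp3 stood at 34.3 CPM against 1.44 to 2.32 CPM elsewhere, Samhd1 at 113 against 13.1 to 34.3 CPM and Vim at 430 against 75.2 to 242 CPM. Cd4 stood at 372 CPM there, while Cd8a (56 CPM against up to 110 CPM) and Cd8b1 (47.5 CPM against up to 89.7 CPM) lay below the highest other library. Mature T cells in the sorted sample may be a source, although the sort excluded cells with surface CD4 or CD8, several of the listed genes are also expressed in DN3 cells, and a change within DN3 cells of that mouse was not tested.

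Immediate-early and heat-shock genes were low in control replicate 1 and both p45-deficient libraries and high in the other 3. Genotype alone is argued against, since control replicate 2 exceeded control replicate 1 by a median log2 ratio of 1.58, in 24 of 25 genes. A handling difference that groups control replicate 1 with the p45-deficient and control replicate 2 with the Tcf1-deficient libraries may contribute. The p45-deficient libraries differed from control replicate 1 by a median absolute log2 difference of 0.79 and the Tcf1-deficient from control replicate 2 by 0.34, and because each mutant lies wholly on one side, handling and genotype cannot be told apart for the difference between the mutants.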
